A study of Mus musculus with 6 samples.

How the data were processed

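Genome-wide H3K27ac was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in 6 hippocampal libraries from C57BL/6 mice at postnatal day 14. There were 3 libraries from mice given N-bc2S1P and 3 from mice given saline. Per the labels' protocols, tissue was fixed in 1% formaldehyde and sonicated, chromatin was precipitated with an H3K27ac antibody, and the libraries were sequenced as single-end reads. Groups and replicate numbers were taken from the sample labels. The labels call the libraries replicates without saying that they came from separate animals, so p-values measure the spread between these libraries, which may in part be technical.

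The deposited values are whole-number counts per consensus peak and library, in 1 matrix of 28799 peaks. Per the labels, reads were trimmed and aligned to mm10 (GRCm38), broad peaks were called and a consensus set was counted. The submitters' processing notes name Trim Galore, Bowtie2, MACS2, DiffBind and DESeq2 without versions or roles. How the consensus was formed, whether duplicate reads were removed and whether an input control was used are not given in the sources used here. Every library column of the matrix was matched to a label by its name, and 0 other sample columns were present. Coordinates are given as deposited, and the file does not state whether they count from 0 or from 1.

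Total counts ranged from 20718404 to 26391401 per library. The common biological coefficient of variation was 14.0%. With this depth and spread, simulated data with 200 changed peaks (50 for each fold, higher or lower) were tested before the real counts. The peak test recovered 8% of changes of 1.25-fold, 16% of 1.5-fold, 84% of 2-fold and 98% of 4-fold, with 0 false calls. The gene test, on simulated counts for 8645 genes, recovered 8%, 50%, 96% and 98% at those folds, with 1 false call. In both simulations all rows shared a common dispersion, and the changed rows were drawn from those above a low count. Adjustment is stricter where fewer rows change, so with few real changes less may be recovered. In 20 simulated draws, a single list of 15 genes shifted by 0.3 on the log2 scale was tested with limma's camera. Its unadjusted p was under 0.05 in 20 draws. These draws used independent normal noise in place of counts. The real test was harder, with adjustment over 17 lists, many of fewer than 15 measured members, so its power is not known from these draws. Small differences were therefore mostly below what the peak test detects. All pairs of libraries differed by more than counting noise, with a chi-square per degree of freedom of 17.6 or more, so no pair was treated as copies of one library. This does not show that they are biological replicates.

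The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM factors, edgeR's filter on low counts, no covariate and Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. Standard errors were derived from the fitted log2 fold change and its F statistic. CPM values of peaks are the deposited counts scaled to each column's total. Those of genes are scaled to the column total of the gene table, which leaves out peaks in no gene and counts a peak once for each gene it overlaps, so CPM values of peaks and genes are not on one scale. Peaks were placed on GRCm38 with GENCODE M21. A peak was called promoter when it overlapped the 1000 bp on either side of a transcription start site (TSS) of a protein-coding gene or lncRNA, otherwise genic when it overlapped a gene body, and otherwise intergenic. Gene counts were sums over peaks overlapping the gene body or the 2500 bp upstream of its start. Gene lists (26, of which 13 were cell type markers) were tested with limma's camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 where at least 5 members were measured. Camera with an estimated correlation and fry were run beside it. Totals and chromosome shares were compared by an exact permutation test over 20 assignments, for which the smallest possible p is 0.1.

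The peaks, genes and list members to name were set by a rule fixed before the data were examined. Among peaks past the threshold with fully separated groups, the 10 with the largest fold and the 10 with the smallest p in each direction were to be named. If fewer than 10 passed in all, the 10 peaks with the smallest p were to be named with their values and not called changed, and the same held for genes. For each list, the 2 members with the smallest p were given as values, or 3 where a member was called. Some of these members are not reported here. Actb, Gapdh and the S1pr genes were controls. S1pr3 was the one S1pr gene with a tested value by position, and the others were not analysed here. The matrix held 0 peaks on the Y chromosome, so its share of counts could not be compared.

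Because each peak ID also carries a gene symbol or the word intergenic, the IDs were compared with the positions. Symbols were looked up in GENCODE M21, and in RefSeq names and synonyms. For chance values, symbols were permuted over the peaks and the intervals were placed at random along their own chromosomes, 1000 times each. The random intervals started at least 100000 bp from either chromosome end. Peaks lying wholly over unsequenced bases (N) of the GRCm38 sequence were counted. Genes taken from the symbol in the ID were used as an added assignment beside the planned one by position. The checks of widths, of positions and of Notch pathway genes were chosen after the values were seen. They used Python 3.11.15 with scipy 1.17.1.

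Alternatives were other normalizations (DESeq2's median-ratio factors, column totals, loess offsets), DESeq2's Wald test (DESeq2 1.42.0), limma-voom, other count filters, peaks of at least 1000 bp, a block on the replicate number, leaving out each library, other gene assignments (promoter peaks only, or the nearest TSS within 50000 bp) and other promoter definitions. After the data were seen, fits without peaks over unsequenced bases, without overlapping peaks and without the 6 peaks with IDs ending in Promoter_Peak were added. Pseudocount settings, meant for values other than counts, did not apply.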

Results

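H3K27ac, an acetylation mark on histone H3 found at active promoters and enhancers, was measured in the hippocampus of young mice at postnatal day 14. The single contrast set 3 libraries from mice given N-bc2S1P against 3 libraries from mice given saline. N-bc2S1P is a code name that the labels do not explain. The deposited counts summed to 23520291, 20718404 and 26391401 in N-bc2S1P replicates 1, 2 and 3, and to 22377446, 24734828 and 21699009 in saline replicates 1, 2 and 3. Of the 28799 peaks, 14994 had IDs that named the TSS of a gene, 13799 had IDs that named an intergenic peak, and 6 had IDs that named a gene's promoter. Peaks with TSS IDs had mean counts of 415 to 2798 per library and held 95.5% to 95.6% of all counts. Those with intergenic IDs had mean counts of 0 to 171, so that the ranges of the 2 kinds did not meet.

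The gene symbols in the IDs and the coordinates did not name the same places. Of 8442 peaks with a symbol in the annotation, 399 (4.73%) lay on the chromosome of the named gene, where permuted symbols gave a mean of 390 (355 to 428). None (0) lay within 5000 bp of a TSS of the named gene, and the nearest was 94940 bp away. A further 4090 of the 15000 gene-named peaks (27.3%) carried a symbol found neither in GENCODE nor among RefSeq names and synonyms. Peaks with TSS or promoter IDs lay within 2500 bp of any TSS in 10.06% of cases, against 10.2% for random placement (9.71% to 10.6%), and 46.6% of the peaks with intergenic IDs overlapped a gene. In all, 853 peaks, with 3790200 counts (2.72%), lay wholly over bases that are unsequenced in GRCm38, where no read can align. Gene names below are therefore given as taken from the ID or as taken from the position, and neither can be read as H3K27ac at that gene.

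The main comparison asked which peaks differed in H3K27ac between N-bc2S1P and saline. The 6 peaks with promoter IDs had 71.7 to 121 times the depth-scaled counts (CPM) in N-bc2S1P, and their symbols were all of Notch pathway genes. They named Hes1, Hes5 and Hey1, transcriptional repressors induced by Notch signalling, Jag1, a Notch ligand, Maml1, a coactivator of the Notch transcription complex, and Dtx2, a Deltex family ubiquitin ligase. Counts in these peaks were 1257 to 2532 in the N-bc2S1P libraries and 14 to 26 in the saline libraries. A further 2 peaks, with intergenic IDs, had lower depth-scaled counts in N-bc2S1P and passed narrowly, but not once the 6 peaks were left out. No other peak passed. In total 8 of 27825 tested peaks passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 6 higher and 2 lower, and 974 peaks had too few counts to be tested.

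The peak with the smallest p carried the Dtx2 ID and lay at chromosome 8, 70601000 to 70602948, overlapping Ssbp4, while Dtx2 itself lies on chromosome 5. This peak had 90.7 ± 7.76 CPM in N-bc2S1P and 0.871 ± 0.0359 CPM in saline (SD, n = 3 each), a log2 fold change of 6.69 (SE 0.24, edgeR adjusted p = 3.29e-33). The Hes5 peak lay at chromosome 4, 150701000 to 150704971, in no gene and 4257938 bp from the Hes5 TSS, with 91.0 ± 13.8 against 0.750 ± 0.126 CPM and the largest log2 fold change, 6.90 (SE 0.25, edgeR adjusted p = 3.29e-33). The Hes1 peak, at chromosome 16, 30601100 to 30604047, overlapped Fam43a and lay 538189 bp from the Hes1 TSS. Its CPM was 69.8 ± 2.99 against 0.974 ± 0.00823, a log2 fold change of 6.15 (SE 0.23). The Maml1 peak, at chromosome 10, 80001000 to 80004338, overlapped Abca7, while Maml1 itself lies on chromosome 11. Its log2 fold change was 6.33 (SE 0.24), from 65.0 ± 3.79 against 0.804 ± 0.142 CPM. The Jag1 peak, at chromosome 2, 136861300 to 136865165, overlapped no gene and lay 253412 bp from the Jag1 TSS, with a log2 fold change of 6.30 (SE 0.24). The Hey1 peak, at chromosome 14, 52901200 to 52904032, overlapped no gene, while Hey1 lies on chromosome 3, and its log2 fold change was 6.28 (SE 0.24). The edgeR adjusted p of these 4 peaks was 5.13e-32 or, for Hey1, 5.47e-32.

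**Figure D1:**
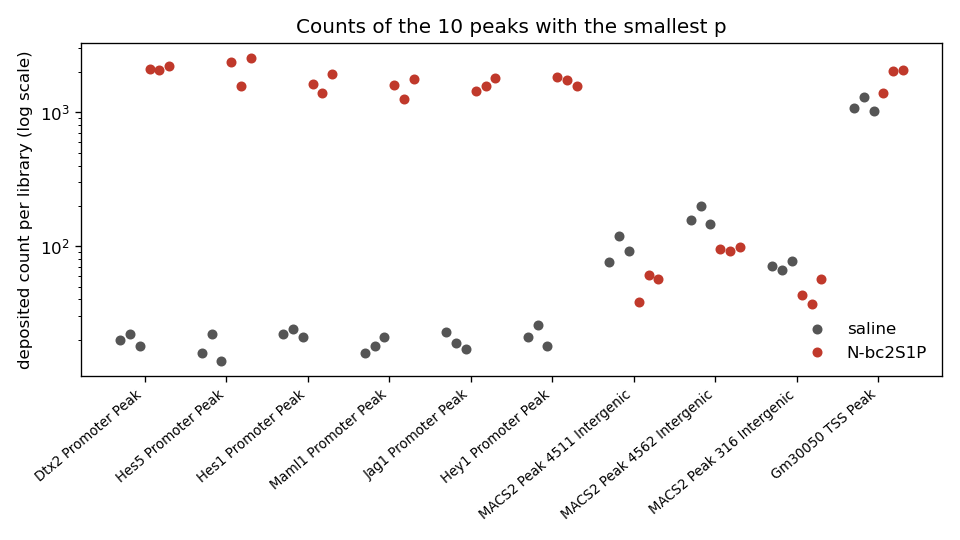
Deposited counts per library (log axis) of the 10 peaks with the smallest p in edgeR's test, with saline libraries in grey and N-bc2S1P libraries in red, 3 points each. The 6 peaks with promoter IDs had 14 to 26 counts in saline and 1257 to 2532 in N-bc2S1P, whereas the other 4 differed by less than 2-fold between group means.

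Another 26 Notch pathway genes, chosen after the values were seen, were named in TSS IDs, among them Notch1, Rbpj and Dll1. Their median log2 fold change was 0.01, with quartiles of -0.10 and 0.13, and they ranged from -0.42 for Mfng, a Fringe glycosyltransferase, to 0.30 for Maml2. The Notch1 peak had a log2 fold change of 0.14 (SE 0.17), the peak of Rbpj, which binds DNA in the Notch complex, 0.00 (SE 0.17), and that of the ligand Dll1 0.30 (SE 0.17). Of the 26, 0 passed in edgeR and 0 in DESeq2, 1 (Mfng) had an unadjusted p under 0.05, and the smallest edgeR adjusted p was 1.00. No peak with a TSS ID passed in edgeR, so the 0 in edgeR was fixed before these 26 were chosen and does not test the pathway. The control peaks by ID did not pass either, with log2 fold changes of -0.22 (SE 0.17) for Gapdh and 0.18 (SE 0.18) for Actb.

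Both lower peaks were close to the threshold. MACS2_Peak_4511_Intergenic, at chromosome 15, 25789370 to 25791780, had 2.24 ± 0.668 CPM in N-bc2S1P and 4.15 ± 0.712 in saline, a log2 fold change of -0.91 (SE 0.19, edgeR adjusted p = 0.0401). MACS2_Peak_4562_Intergenic, at chromosome 9, 73485408 to 73486296, had 4.06 ± 0.364 against 7.26 ± 0.662 CPM, a log2 fold change of -0.84 (SE 0.18, edgeR adjusted p = 0.0411). By position both lay within genes. The first passed in 10 and the second in 8 of 17 alternative fits. Both calls ended without the 6 peaks with promoter IDs (edgeR adjusted p = 0.164 for each) and without a count filter (0.191 and 0.0557). Neither passed in edgeR without N-bc2S1P replicate 1 or 3 or without saline replicate 2 or 3. In that order, the edgeR adjusted p of the first was 0.886, 0.658, 0.550 and 0.157. That of the second was 0.364, 0.708, 0.478 and 0.0805. Without N-bc2S1P replicate 2 (0.0112) or saline replicate 1 (0.00740) the first alone passed. The other peaks among the 10 with the smallest p did not pass: MACS2_Peak_316_Intergenic had a log2 fold change of -0.69 (edgeR adjusted p = 0.622) and the peak with the Gm30050 ID one of 0.67 (edgeR adjusted p = 0.888).

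All remaining peaks had log2 fold changes between -0.69 and 0.70, with a median SE of 0.18 over tested peaks. An unadjusted p under 0.05 was found for 1219 peaks (4.38%). The 3 values of one group lay fully above or below those of the other in 2763 peaks (9.93%), where chance gives 10%. All 8 called peaks were among them. DESeq2's Wald test called 13 peaks, 8 higher and 5 lower, including the 6 with promoter IDs.

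**Figure D2:**
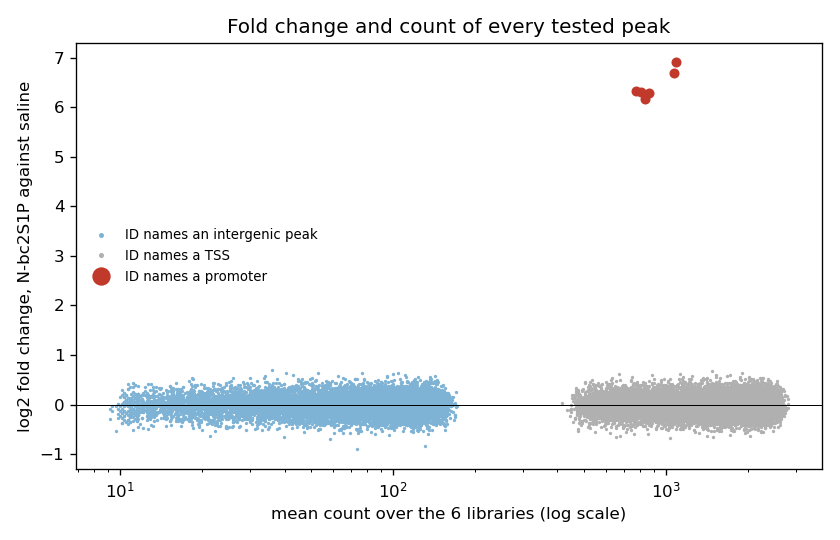
Log2 fold change (N-bc2S1P against saline) of each of the 27825 tested peaks against its mean count over the 6 libraries (log axis), with the 6 peaks with promoter IDs in red, TSS IDs in grey and intergenic IDs in blue. The red points lie at 6.15 to 6.90, all peaks that did not pass lie between -0.69 and 0.70, and TSS and intergenic IDs occupy separate ranges of count.

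Summed over each gene by position, 3 genes were higher in N-bc2S1P and 0 lower among 8461 tested. They were Fam43a (log2 fold change 6.16, SE 0.23), Abca7, a lipid transporter gene (6.34, SE 0.24), and Ssbp4 (5.68, SE 0.21), each with an edgeR adjusted p of 3.12e-19. Each call came from the peak with the Hes1, Maml1 or Dtx2 ID that overlapped the gene. Scaled to the summed counts of the gene table, a smaller total than that of the peaks, Fam43a had 128 ± 5.41 CPM in N-bc2S1P and 1.78 ± 0.0166 in saline, Abca7 119 ± 6.76 against 1.47 ± 0.260, and Ssbp4 169 ± 14.7 against 3.27 ± 0.281 (SD, n = 3 each). The next genes by p did not pass: Rspo3, a secreted activator of Wnt signalling, had a log2 fold change of -0.64 (SE 0.16, edgeR adjusted p = 0.819), Grifin -0.66, Cdh19 -0.58, Gtf2ird2 -0.59, Gm38161 -0.59, Ube2cbp 0.56 and Dnaic2 0.52 (edgeR adjusted p = 0.986 for each of these 6). S1pr3, a sphingosine-1-phosphate receptor gene, had 4.05 ± 0.690 against 3.83 ± 0.112 CPM and a log2 fold change of 0.09 (SE 0.16, edgeR adjusted p = 0.990). Of all genes, 414 (4.89%) had an unadjusted p under 0.05, 204 higher and 210 lower, and DESeq2 called 6, of which 3 were lower. With genes taken from the ID, the 6 called of 15000 in edgeR were Dtx2, Hes1, Hes5, Hey1, Jag1 and Maml1. By ID, 712 genes had an unadjusted edgeR p under 0.05, and DESeq2 called 18, 12 higher and 6 lower. With promoter peaks alone, 0 of 2204 genes passed in edgeR (114 at an unadjusted p under 0.05, 3 called by DESeq2).

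The gene lists asked whether markers of a cell type or genes of one function moved together. By position, 17 of the 26 lists had at least 5 measured members, 0 passed limma's camera, and 0 had an unadjusted p under 0.05. The smallest adjusted p was 0.614, or 0.829 with an estimated correlation and 0.358 with fry. Of the 184 genes on any list with a value, 0 passed over all genes in edgeR or in DESeq2 and 10 had an unadjusted p under 0.05. Adjusted over the list alone, 1 member passed. All named list members below had an edgeR adjusted p of 0.986 or more over all genes.

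Among lists of neuronal function, the 22 measured genes of the glutamatergic synapse had a median log2 fold change of 0.02 (camera adjusted p = 0.865), with 0.16 (SE 0.09) for Gria4, an AMPA receptor subunit, and 0.13 (SE 0.09) for Nlgn1. The 14 of the GABAergic synapse had a median of 0.01 (0.977), with Gphn, the scaffold protein gephyrin, at 0.28 (SE 0.12) and Gad1 at 0.35 (SE 0.16). The 17 presynaptic release genes had a median of 0.05 (0.614), with Pclo at 0.17 (SE 0.08) and Stx1a at 0.30 (SE 0.17). The 21 voltage-gated channel genes had a median of -0.01 (0.977), with Kcnq5 at -0.15 (SE 0.08) and Cacna2d2 at 0.30 (SE 0.17). For the 10 genes of neurotrophin and CREB signalling the median was -0.01 (0.977), with Camk4 at -0.24 (SE 0.10) and Ngfr at 0.14 (SE 0.12).

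Among cell type lists with at least 5 measured members, the lowest median was that of the 5 microglial genes, -0.10 (camera adjusted p = 0.614), with Cx3cr1 at -0.18 (SE 0.16). The highest among these lists was that of the 5 genes of myelinating oligodendrocytes, 0.21 (0.614), with Aspa at 0.25 (SE 0.17) and Myrf at 0.21 (SE 0.16). Astrocyte markers (5 measured) had a median of 0.19 (0.614), with Fgfr3 at 0.22 and the water channel gene Aqp4 at 0.36 (SE 0.21). Oligodendrocyte precursors (6) had -0.01 (0.977), with Ptprz1 at 0.17 and Gpr17 at -0.22, endothelial cells (7) 0.01 (0.865), with Slco1a4 at 0.31 and Tek at 0.09, and GABAergic interneurons (7) -0.01 (0.977), with Gad1 at 0.35 and Adarb2 at -0.07. Dentate granule neurons (5) had a median of -0.06 and a mean of 0.01 (0.977), with Stxbp6 at 0.25 and Dsp at 0.15.

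Of the remaining lists, the 11 measured sphingosine-1-phosphate and sphingolipid genes had a median of -0.03 (camera adjusted p = 0.791), with Sgms1, a sphingomyelin synthase, at 0.17 (SE 0.08) and Sptlc2, a serine palmitoyltransferase subunit, at -0.33 (SE 0.16). The 7 glucocorticoid and stress response genes had 0.11 (0.866), with the glucocorticoid receptor gene Nr3c1 at 0.22 (SE 0.11) and Fkbp5 at -0.26 (SE 0.17). The 12 histone acetylation genes had 0.01 (0.880), with the deacetylase gene Hdac9 at -0.18 (SE 0.08) and the acetyltransferase gene Kat5 at 0.33 (SE 0.17). The 5 perineuronal net and matrix genes had -0.03 (0.977), with Ptprz1 at 0.17 and Tnr at -0.10, while their mean was 0.00. The 7 cholesterol synthesis genes had a median of 0.11 (0.614).

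Too few members were measured to test 9 lists. Excitatory pyramidal neurons (4 measured) included Mpped1 at -0.19 and Pou3f1 at -0.08, thalamus and striatum (4) Drd1 at -0.26 and Ppp1r1b at -0.15, and housekeeping genes (3) Tfrc at 0.29 and Eef1a1 at 0.25. Immediate early genes (3) included Klf4 at -0.14 and Nr4a3 at 0.06, and the inflammatory response (3) Ptgs2 at -0.10 and Irf8 at 0.05. Mural cells and fibroblasts (2) were Tagln at 0.36 and Dcn at 0.02, and choroid plexus and ependyma (2) Clic6 at 0.09 and Otx2 at 0.04. The 2 measured blood cell genes had a median of -0.21. Of the neural progenitor list, 0 members had a value by position.

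By genomic class, the called peaks lay in genes (3 higher and 2 lower of 11153 tested) or in intergenic sequence (3 higher of 14534). Of 2138 tested promoter peaks, 0 passed in edgeR, with 97 at an unadjusted p under 0.05, and DESeq2 called 2, both lower. The promoter share of called peaks was thus 0 of 8, with an exact 95% confidence interval of 0% to 36.9%, against 7.68% of tested peaks. With promoters taken as 2500 bp on either side of a TSS, 25% (2 of 8) of the called peaks were promoter peaks. The share of tested peaks under this wider definition is not given here, so the 25% cannot be set against the 7.68%. Median log2 fold changes were -0.01 for promoter, 0.00 for genic and 0.00 for intergenic peaks, with 48.7%, 50.5% and 49.5% of peaks above 0. Too few peaks were called in either direction for Fisher's exact test, which was set to need 10. At an unadjusted p under 0.01, promoters were 6 of 115 higher peaks (Fisher's exact p = 0.383) and 9 of 123 lower peaks (p = 1).

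The log2 total count was 24.48 ± 0.17 in N-bc2S1P and 24.45 ± 0.10 in saline (SD, n = 3 each), a difference of 0.03 (exact permutation p = 0.8, two-sided, where the smallest possible is 0.1). With single libraries left out, this difference ranged from -0.05 (without N-bc2S1P replicate 3) to 0.12 (without N-bc2S1P replicate 2). The X chromosome held 4.91% ± 0.0242 of counts in N-bc2S1P and 4.90% ± 0.0293 in saline (SD, n = 3 each, exact permutation p = 0.6, adjusted 0.933 over 20 chromosomes). Chromosome 8 held 4.88% ± 0.00695 in N-bc2S1P and 4.91% ± 0.00442 in saline (SD, n = 3 each), with all 3 values of one group below those of the other (exact permutation p = 0.1, the smallest possible, adjusted 0.933). With this floor no chromosome could pass after adjustment, so the test cannot exclude differences between the groups. Peaks per chromosome ranged from 1358 on chromosome 9 to 1537 on chromosome 11 and did not follow length: chromosome 1, of 195 Mb, held 1458 and chromosome 19, of 61.4 Mb, held 1414 (Spearman's rho of length and peak number, across chromosomes, 0.0624).

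**Figure D3:**
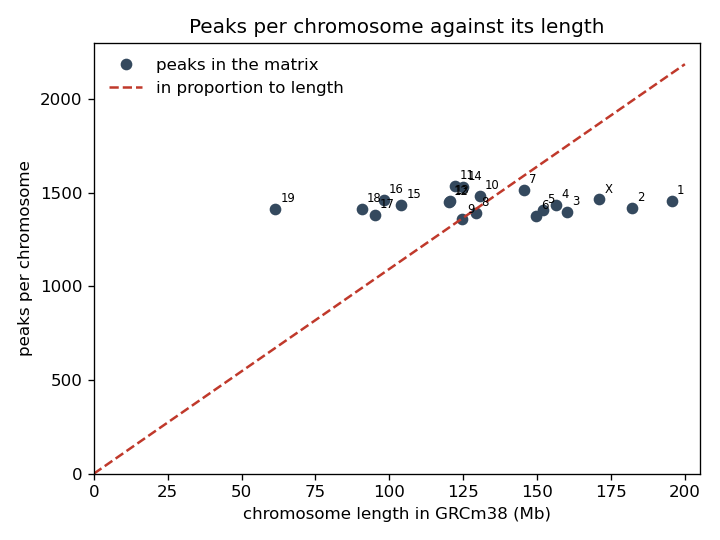
Number of peaks on each of 20 chromosomes against the length of the chromosome in GRCm38 (Mb), with a dashed line for numbers in proportion to length. The points lie between 1358 and 1537 over the whole range of lengths.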

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

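The 6 peaks with promoter IDs passed in all 18 alternative fits that kept them, with log2 fold changes of 6.12 to 7.05. The 2 lower peaks kept their direction in the 17 alternatives that gave each an adjusted p, at -1.13 to -0.72 for MACS2_Peak_4511_Intergenic and -0.91 to -0.77 for MACS2_Peak_4562_Intergenic, but not always their call. Of lower peaks, edgeR called 0 without a count filter and 0 to 1 with each library left out, limma-voom called 1, and DESeq2's Wald test called 5. The 5 were MACS2_Peak_4562_Intergenic and 4 peaks with TSS IDs, and MACS2_Peak_4511_Intergenic was not among them. Without any one of N-bc2S1P replicates 1 and 3 and saline replicates 2 and 3, 0 lower peaks were called, and without either of the other libraries 1. DESeq2 called 13 peaks in all. For these changes the cause was not tested. By construction, peaks above the median count (0 lower called) leave out both lower peaks, and peaks of at least 1000 bp (1 lower called) leave out the second. Without the 6 peaks, an alternative added after the data were seen, edgeR called 0 peaks, 0 higher and 0 lower (smallest adjusted p 0.164, 1212 at an unadjusted p under 0.05; DESeq2 called 6), since the adjusted p of the next peaks depends on how many lie above them. By position, DESeq2 called 6 genes (the cause was not tested), edgeR 1 among genes above the median count (Ssbp4) and 0 from promoter peaks alone, where none of the 6 peaks lies. Fam43a and Abca7 had lower CPM than Ssbp4 in both groups, so the cut at the median may have left them out untested. Taking the nearest TSS gave 6 genes in edgeR and the symbol in the ID 6 genes, one per peak. By ID, DESeq2 called 18 genes, 12 higher and 6 lower, and the cause was not tested. With the replicate number as a block, 7 peaks (1 lower), 3 genes and 0 lists were called. No shared deviation of same-numbered libraries was seen, with correlations of 0.0020, 0.0002 and 0.0039. These values cannot show whether libraries were paired or handled together by number. The lists past the threshold numbered 0 in all 12 alternatives. In simulated data with 200 changed peaks and a common dispersion, 16% of 1.5-fold changes of peaks and 84% of 2-fold changes were recovered. With fewer changed peaks the adjustment is stricter, so recovery in the real data may be lower.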

Other observations

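The tests of IDs against positions, of widths, of start coordinates and of the other Notch pathway genes were chosen only after the results were seen. The test of single libraries and the splits of the libraries were planned.

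With genes taken from the symbol in the ID, an assignment added after the data were seen, 6 of the 26 lists had 5 or more members and 0 passed limma's camera (smallest adjusted p 0.621, 0.727 with an estimated correlation). The 15 housekeeping genes had a median log2 fold change of -0.03 and a mean of 0.02, with Tbp at 0.34 (SE 0.17) and Sdha at 0.32 (SE 0.18). The 15 inflammatory genes had a median of 0.07, with Ccl4 at 0.29 (SE 0.18), and the 15 voltage-gated channel genes one of -0.05, with Cacna1g at -0.47 (SE 0.17) and Kcna2 at 0.36 (SE 0.17). Among 8 glutamatergic synapse genes Cacng2 had 0.49 (SE 0.18), among 11 GABAergic synapse genes Gabrd had 0.20 (SE 0.17), and among 7 mural and fibroblast genes Acta2 had 0.29 (SE 0.17). Of the list members, 1 passed over all genes, Hes5 among the progenitor genes, beside Sox2 at 0.11 (SE 0.18) and Sox4 at 0.03 (SE 0.18). Adjusted over the list alone, Klf9 on the stress response list also passed, at -0.47 (SE 0.18), but only 2 members of that list were measured. Over all genes, the edgeR adjusted p of Klf9 was 0.988.

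The first pattern is that gene names and positions were unrelated. A different genome build would keep most genes on their chromosome, and 4.73% of named peaks were there, so the tables argue against it. Symbols shuffled among real peak positions would leave peaks with TSS IDs near some TSS more often than random intervals, and 10.06% were, below the upper bound of 10.6% for random placement. Positions placed at random along each chromosome stay open: 853 peaks lay wholly over unsequenced bases, within the 743 to 854 of random placement, where aligned reads would give none. The random starts were kept 100000 bp from chromosome ends, so any unsequenced bases nearer the ends were mostly left out of that range. The 853 peaks held 3790200 counts where no read can align, which argues against their coordinates coming from peak calls on reads aligned to GRCm38. For the remaining peaks, a candidate explanation, stated as a hypothesis, is that their coordinates do not come from such peak calls either. No biological explanation was tested.

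The second pattern is the set of 6 peaks with promoter IDs, higher by 71.7 to 121 times. A rise across the Notch pathway was the biological explanation looked at. If the names hold, the other 26 pathway rows had a median log2 fold change of 0.0087 and quartiles of -0.10 and 0.13. Those rows did not rise with the 6 peaks. They were chosen when every peak that did not pass was already known to lie between -0.69 and 0.70. No set of such rows could have shown a rise like that of the 6, so they do not test the explanation. If the names do not hold, the 6 peaks are not at pathway genes either, and H3K27ac at the Notch genes themselves was then not measured. A single library does not carry the difference, since the largest adjusted p with any library left out was 3.32e-25 in edgeR. All 6 start coordinates are multiples of 100, against 1.12% of the other 28793 (exact binomial p = 1.99e-12). The step of 100 was chosen after the starts were seen, so this p describes them and does not test an origin separate from the other peaks, which stays open.

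The third pattern is that counts did not follow peak width. Reads collected over intervals would give wider peaks more counts, and across peaks of each ID kind Spearman's rho was at most 0.00762 in size in any library, which argues against it; peaks are not independent replicates. Widths ran from 500 to 3000 bp for TSS IDs and from 300 to 2500 bp for intergenic IDs. Their distance from an even spread was at most 0.754 of the 95% point of simulated even draws, so that widths drawn evenly between fixed limits may account for them. How the matrix was made is not shown by any of these tests, no biological explanation was tested, and until that is known the fold changes above describe the deposited numbers and may not describe H3K27ac.

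The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 8 peaks and the highest other 0 (1 of 10 splits as large), and it gave 3 genes where the highest other gave 0 (1 of 10). For lists, the real split gave 0 and the highest other 0, so 10 of 10 were as large. Each other split had 1170 to 1277 peaks and 351 to 415 genes at an unadjusted p under 0.05, against 1219 and 414 in the real one.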
